A study of Mus musculus with 4 samples.

How the data were processed

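Transcript levels were measured in cultured mouse bone marrow-derived macrophages with an Affymetrix whole-transcript array, 1 array per group. The 4 groups were wild type and Hilpda knockout, each after 12 h and after 24 h with 600 µM palmitate and oleate in a 1:2 ratio on albumin. Wild type here means floxed Hilpda without deletion, and knockout means littermates whose macrophages lack the gene. Per the labels' protocols, RNA of 3 samples was pooled for each array and labelled with biotin as sense-strand target. Each sample was assigned to its group from the genotype and incubation time in its labels.

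The deposited values are log2 expression per probe set, made by the authors with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale. It forces the arrays to near-equal distributions, so a shift of all transcripts together would not be visible. That the scale is log2 was read from the values, which ran up to 13.2 with medians of 2.70 to 2.73 in the 4 columns. The annotation used by the authors is not given in the sources used here. The value table held 0 columns that could not be matched to a sample.

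Of 41345 probe sets, 25335 had a gene in the platform annotation, 23521 of them with 1 symbol and 1814 with several, and 16010 had none listed. Probe sets with several symbols or none were not used for named genes. Of the probe sets with 1 symbol, 23328 matched the RefSeq gene table of mouse assembly GRCm38.p6, and 0 of these carried another symbol there. That table was used only for names and for gene order around Lyz2. Where a gene had more than 1 probe set (1082 of 22180 genes), the one with the highest mean over the 4 arrays was taken. Genes with a mean level at or above the 40th percentile, a log2 value of 2.44, were kept, which left 13354 genes.

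A genotype difference is the log2 value in knockout minus that in wild type at the same time, and a time difference is the value at 24 h minus that at 12 h in the same genotype. With 1 array per group there was no replicate error at a single time or within a genotype, so these differences were not tested. Genes with a difference of at least 1.5-fold in size were counted, and the central 95% range over genes was given. The 2 genotype differences use no array in common, nor do the 2 time differences, so their overlap was set beside that of independent lists. A genotype difference and a time difference that use the same array share its chance values. The precision is limited by the number of arrays. As a yardstick of noise at background signal, the spread of the differences was taken over 1409 olfactory, vomeronasal and trace amine receptor genes, without the level filter.

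The comparisons, the level filter, 29 gene lists of pathways and cell types, the rule for named genes and most alternatives were fixed before the data were examined. For each list with at least 5 members past the level filter, the median difference was placed among 10000 random lists of the same size matched on mean level in 20 bins. A list was said to stand apart at both times when its percentile was at or under 2.5, or at or above 97.5, on the same side in both comparisons. Such a percentile describes these arrays and is not a p-value. Several lists share members, among them Fabp4, Plin2 and Atp6v0d2.

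The named genes were Hilpda, the 10 highest and 10 lowest of each pairwise comparison, and up to 15 highest and 15 lowest among those past 1.5-fold at both times, ranked by the smaller of the 2 differences. Clone, predicted-gene and small RNA names were passed over. From each list came up to 4 members past 1.5-fold in the same direction at both times and up to 3 with the largest time differences. The 5 highest and 5 lowest changes of the genotype difference, sex-linked genes, Actb, Gapdh and Lyz2 completed the rule. Other list members, and genes picked from those past the 60th percentile of level, were named as examples after their values were seen.

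Alternatives were no level filter, a filter at the 60th percentile (4.20 on the log2 scale, 9089 genes), fold rules of 1.3 and 2, median centring, quantile normalization, a loess on level with a span of 0.3, and the mean over a gene's probe sets. A limma fit of genotype with time as an added term, leaving 1 residual degree of freedom, was the only test across genes, with Benjamini-Hochberg adjustment. Counts without the mesenchymal genes were added after seeing the data. The steps were tested on simulated data for 13354 genes with 200 changed between the genotypes. The 1.5-fold rule at both times recovered 97% of the genes changed 2-fold and 100% of those changed 4-fold, and 10 unchanged genes passed it. The limma fit recovered 83% and 100%, with 1 unchanged gene called. Each simulated effect was the same at both times, and the noise was normal, independent between genes, with an SD set by level. In the real arrays effects can differ between the times and noise between genes, so these rates may not hold there. Of 100 unchanged random lists, 4 lay outside the central 95%, a share that random drawing builds in. The simulated genes varied independently, so this count does not tell how often lists of genes that vary together would lie outside.

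The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.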

Results

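HILPDA is a small protein of lipid droplets that inhibits adipose triglyceride lipase. The arrays asked how its absence in macrophages alters the transcript profile of cells loaded with palmitate and oleate, a saturated and a monounsaturated fatty acid. Marrow cells had been turned into macrophages with medium conditioned by L929 cells, a source of the growth factor CSF1. Wild-type and knockout cells were each profiled after 12 h and 24 h, with 1 array per group and RNA of 3 samples pooled on each. There were therefore no replicates within a group, and the differences at a single time or within a genotype were not tested. The only test across genes took both times together, with 1 residual degree of freedom. That residual is the change of the genotype difference between the times and not an error between replicates. Cells without fatty acids were not analysed here, so the time differences do not separate the response to fatty acids from time in culture. Across all 41345 probe sets the arrays correlated pairwise at 0.984 to 0.988 (Pearson). Over the 13354 genes kept, the wild-type 24 h array correlated at 0.987 and 0.986 with the 12 h arrays of wild type and knockout, and the knockout 24 h array at 0.991 with both. Over the 1409 receptor genes taken as background, the genotype difference had an SD of 0.276 on the log2 scale at 12 h and 0.30 at 24 h, and 4.47% and 5.68% of them lay past 1.5-fold.

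Hilpda itself was lower in the array labelled knockout by a modest amount at 12 h, and at 24 h its difference lay well inside the central 95% of genes. Its log2 level was 5.93 in wild type and 5.41 in knockout at 12 h, a difference of -0.51 or 1.43-fold, and 305 of the 13354 genes kept had a difference as low or lower. At 24 h the levels were 5.47 and 5.27, a difference of -0.20 or 1.15-fold, and 2796 genes were as low or lower. The gene had 1 probe set, and the labels do not say which part of the gene was deleted, so the probe set may lie outside that part and the value is a limited check of the labels. The sex-linked genes were alike in the 4 pools: Eif2s3y, on the Y chromosome, lay between 7.53 and 7.78, Kdm5d between 6.60 and 7.01 and Uty between 7.12 and 7.41, whereas Xist, transcribed from the inactive X, lay between 1.45 and 1.67. The 3 sex-linked genes past the level filter had median genotype differences of -0.05 and -0.15. The 11 reference genes had a median genotype difference of 0.03 at both times, with Actb at 0.05 and 0.01 and Gapdh at -0.00 and -0.11.

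At 12 h, the enzymes of cholesterol synthesis were lower in knockout than in wild-type macrophages. All 19 measured members of that list had a difference below 0, with a median of -0.46 at percentile 0 of the matched random lists. Fdft1, squalene synthase, was at -0.75, Fdps, which makes farnesyl diphosphate, at -0.75, Cyp51, the lanosterol demethylase, at -0.74, and Hsd17b7, a sterol ketoreductase, at -0.83; these were the 4 members past 1.5-fold. Hmgcs1, which makes HMG-CoA, and Sqle, squalene epoxidase, were both at -0.57. Fatty acid synthesis and desaturation genes lay on the same side, with a median of -0.18 over 13 members (percentile 0.02) and 12 of them below 0. Among these, only the stearoyl-CoA desaturase gene Scd1 was past 1.5-fold, at -0.67, and Fasn, fatty acid synthase, was at -0.34.

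Markers of stromal cells and fibroblasts, which macrophage cultures can contain, were also lower in knockout at 12 h. Their median over 9 genes was -0.47 (percentile 0), with all 9 below 0 and the receptor gene Pdgfra past 1.5-fold at -0.62. The collagen genes Col1a1 and Col1a2 were at -0.58 and -0.56. Interferon-stimulated genes had a median of -0.15 over 16 members (percentile 0.70), with 10 below 0 and 6 above. Of these Ifit1 and Ifit3, antiviral proteins, were lower by more than 1.5-fold at -0.70 and -0.62, and Oasl1 was higher at 0.60. Genes of the ATF4-driven integrated stress response lay on the other side, with a median of 0.17 over 21 members (percentile 99.94) and 0 past 1.5-fold. Slc7a11, the cystine transporter, was at 0.39, the serine synthesis genes Phgdh and Psat1 at 0.38 and 0.36, and Ddit3, which encodes CHOP, at 0.35. But 6 of the 21 were below 0, among them Ddit4 at -0.51 and Sesn2 at -0.26, and the mean of the list was 0.10 (percentile 97.0, inside the central 95%). Endoplasmic reticulum chaperones had a median of 0.06 over 19 members (percentile 97.81), a position that moved inside the central 95% after quantile normalization (93.0), after loess (97.0) and against lists not matched on level (91.1).

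Of the 13354 genes, 200 were higher and 187 lower in knockout by at least 1.5-fold at 12 h. These are 2.90% of the genes kept, which is under the 4.47% of the background receptor genes. After quantile normalization 179 were higher and 189 lower. The central 95% of differences ran from -0.50 to 0.49. The highest were Xlr3a at 1.55, Rptoros, a non-coding transcript antisense to Rptor by its name, at 1.48, Slain1 and Bcl2a1a, both at 1.41, Smim22 at 1.28, Hykk at 1.25, Olfr1077-ps1 at 1.09, Ifna1 and Dysf, both at 1.04, and Zfp97 at 1.03. The lowest were Zfp944 at -1.27, the cadherin Fat4 at -1.20, Flg2 at -1.14, the chromatin assembly factor Chaf1a at -1.13, Smok4a at -1.11, Cyp4f37 at -1.09, Spata24 and Ankrd1, both at -1.08, the stromal surface protein Cd248 at -1.06 and Pawr at -1.04. These 20 genes were dim, with mean log2 levels from 2.46 (Flg2) to 4.89 (Zfp944). With the mean over a gene's probe sets, Slain1 was at 0.40, Dysf at 0.41 and Fat4 at -0.52, all under 1.5-fold. Bcl2a1a, Xlr3a and Ifna1 belong to families of near-identical copies whose signals an array can mix, and only 101 genes past the 60th percentile of level, 42 higher and 59 lower, were past 1.5-fold.

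At 24 h, the median genotype difference was below 0 for markers of alternative activation, for macrophage identity genes and for cell cycle genes. The 10 alternative activation markers had a median of -0.38 (percentile 0.09), with 2 lower by more than 1.5-fold: the transcription factor gene Klf4 at -0.71 and the interleukin 4 receptor gene Il4ra at -0.63. Mrc1, the mannose receptor, was at -0.55 and the haemoglobin scavenger receptor gene Cd163 at -0.48. Of the 10 markers 8 were below 0 and 2 above. Arg1, the member farthest from the median, lay on the higher side, and without it the median was -0.44. The 17 macrophage identity genes had a median of -0.14 (percentile 0.27, but 2.60 against random lists not matched on level, inside the central 95%), with the fractalkine receptor gene Cx3cr1 at -1.20 and the integrin gene Itgam at -0.72. Of the 17 genes 11 were below 0 and 6 above. The 28 cell cycle genes had a median of -0.18 (percentile 0.00), with the mitotic kinase gene Plk1 at -0.68 and the kinesin gene Kif20a at -0.65. Of the 28 genes 20 were below 0 and 8 above. Abca1, the cholesterol exporter, was 2.5-fold lower at -1.32, although the 11 LXR target genes to which it belongs had a median of -0.06 (percentile 14.6) and Nr1h3, which encodes LXR alpha, was at 0.67.

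PPAR target genes, markers of lipid-associated macrophages and lysosomal genes had medians above those of most matched random lists in knockout at 24 h. Against lists not matched on level the latter 2 lay inside the central 95% (percentiles 92.6 and 92.3). The 13 PPAR target genes had a median of 0.18 (percentile 99.6), with 2 past 1.5-fold: Fabp4, a fatty acid-binding protein, at 1.48 or 2.79-fold, and the mitochondrial carrier gene Ucp3 at 0.62. The value of Ucp3 lay inside the central 95% of the background receptor genes, which ran up to 0.64. The 13 markers of lipid-associated macrophages had a median of 0.12 (percentile 98.5) and included Fabp4 and, at 0.61, Fabp5. The 24 lysosomal genes had a median of 0.09 (percentile 98.9) with 0 past 1.5-fold, of which the proton pump subunit gene Atp6v0d2 was at 0.54 and Gla, alpha-galactosidase, at 0.51. The 21 genes of beta-oxidation had a median of 0.11 (percentile 97.3, inside the central 95%, but 98.5 by the mean and 97.8 after loess), with Acot13 at 0.67. The 21 genes of the ATF4 list had a median of 0.19 (percentile 99.5): Ddit3 at 0.74, the stress factor gene Atf3 at 0.73 and the folate enzyme gene Mthfd2 at 0.73 were higher by more than 1.5-fold, and Phgdh at -0.92 and Ddit4 at -0.60 lower. The 19 endoplasmic reticulum chaperones had a median of 0.15 (percentile 99.7) with 0 past 1.5-fold.

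The genes of lipid droplets showed little difference between the genotypes. Their median over 15 members was -0.04 at 12 h (percentile 19.5) and 0.08 at 24 h (percentile 86.1). Plin2, the main droplet coat protein of macrophages, was at -0.01 and 0.18, and Pnpla2, the lipase that HILPDA inhibits, at 0.03 and 0.01. Its coactivator gene Abhd5 was the single member past 1.5-fold, at 0.60 at 24 h. Inflammatory genes went both ways at 24 h, with a median of -0.10 over 18 members (percentile 8.96): Il1b at -1.47, the cyclooxygenase gene Ptgs2 at -0.84 and Nlrp3 at -0.67 were lower, and Ccl4 at 1.05 and Saa3 at 0.95 higher. The level of Il1b was 2.59 in knockout at 24 h and 2.39 and 2.32 at 12 h, all near background, so its value rests on the 4.07 of the wild-type 24 h array. At 12 h the median of these 18 genes was -0.04 (percentile 21.3), and 0.06 with no level filter.

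At 24 h, 397 genes were higher and 468 lower in knockout by at least 1.5-fold, which is 6.48% of the genes kept against 5.68% of the background receptor genes. The central 95% of differences ran from -0.66 to 0.62. The lowest were Adgre4, a myeloid adhesion receptor, at -2.92 or 7.57-fold, Gbp7 at -2.21, Pilrb1 at -2.03, Tmem176a at -1.80, the ferroxidase gene Cp at -1.74, the membrane protein gene Ms4a4a at -1.63, the proteoglycan gene Ogn and Olfr1151, both at -1.56, Tmem176b at -1.48, and Il1b. The highest were the muscle genes Acta1 at 1.62 and Myh4 at 1.56, the mitochondrial ribosomal gene Mrpl32 at 1.54, the purine receptor gene P2ry1, 2.83-fold higher, Fabp4, the Wnt antagonist gene Dkk2 at 1.44, Cks2 at 1.39, Yae1d1 at 1.37, Kdr, which encodes VEGF receptor 2, at 1.32 and Gprc5b at 1.31. With the mean over its probe sets Yae1d1 was at 0.65. Some of these differences rest on an array near background, with the level filter at 2.44. In wild type at 24 h Acta1 was at a level of 2.25 and Myh4 of 2.16, and in knockout Olfr1151 of 1.83 and Gbp7 of 2.45. Others rest on the wild-type 24 h array, with the remaining arrays close together. Tmem176a was at 6.84 there, against 5.36 and 5.14 at 12 h and 5.04 in knockout at 24 h. Gprc5b was at 5.01 there, against 6.39, 6.49 and 6.31. Pilrb1, Cp, P2ry1 and Yae1d1 had the same pattern. For Myh4 the knockout 24 h array stood apart instead, at 3.72. Whether such single arrays reflect the genotype was not tested. The stromal markers were lower at this time too, with a median of -0.51 over 9 genes and 4 past 1.5-fold, and 411 genes past the 60th percentile of level, 212 higher and 199 lower, were past 1.5-fold.

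**Figure D1:**
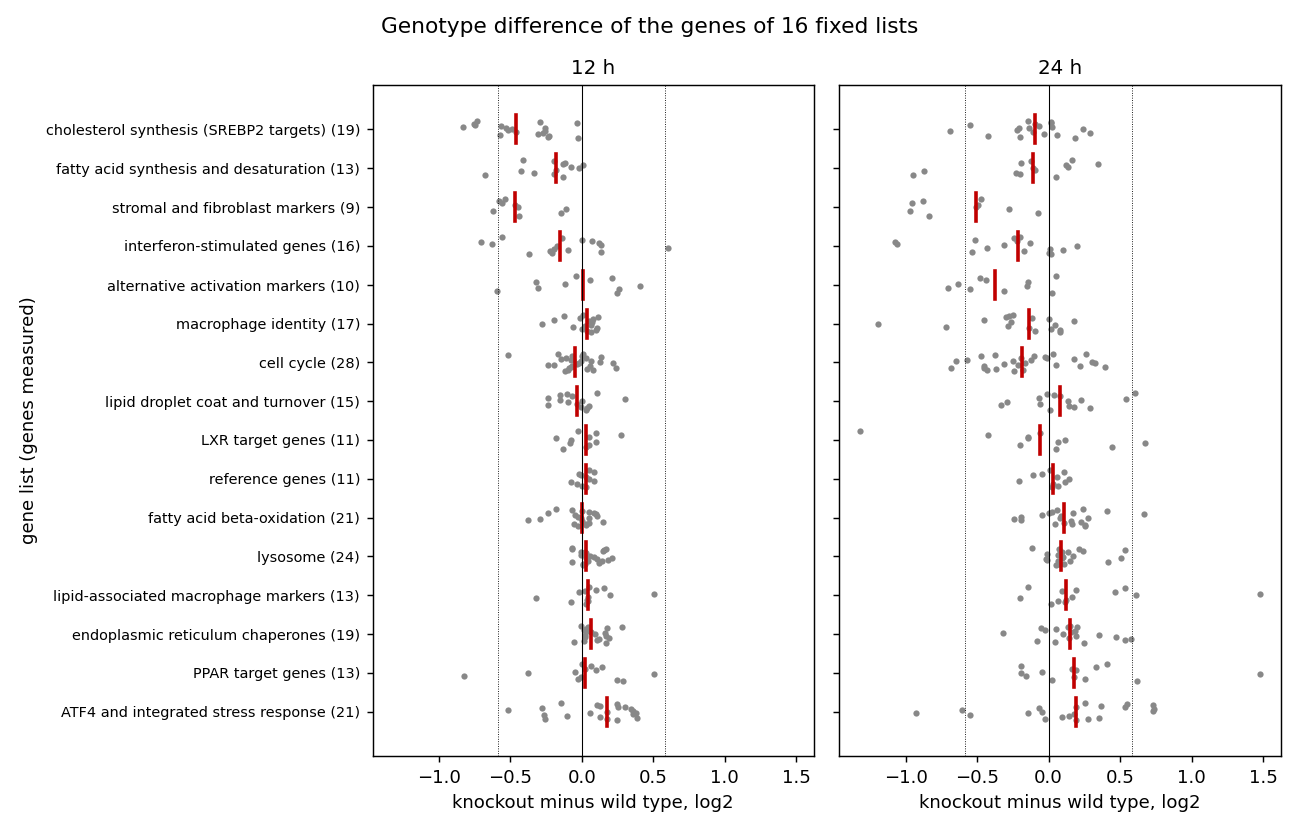
Genotype difference (knockout minus wild type, log2) of each measured gene of 16 fixed lists at 12 h (left) and 24 h (right). Each grey point is 1 gene, red bars are list medians, and dotted lines mark 1.5-fold; the cholesterol synthesis median lies at -0.46 at 12 h and -0.10 at 24 h, and the stromal median at -0.47 and -0.51.

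Between the genotypes, 5 of the 23 lists large enough to be placed stood apart on the same side at both times. Cholesterol synthesis (-0.46 and -0.10; percentiles 0 and 2.37), stromal markers (-0.47 and -0.51; both 0) and interferon-stimulated genes (-0.15 and -0.21; 0.70 and 0.38) were lower in knockout. The ATF4 list (0.17 and 0.19) and the endoplasmic reticulum chaperones (0.06 and 0.15) were higher, the latter not after quantile normalization or loess, and the ATF4 list not by its mean (percentile 97.0 at 12 h). Fatty acid synthesis and desaturation genes missed the rule at 24 h with a median of -0.11 (percentile 3.54), but stood apart at both times by the mean (1.47 at 24 h), after quantile normalization (2.02) and after loess (1.97). In that list at 24 h Scd1 was at -0.95 and Fads2, the delta-6 desaturase gene, at -0.87. Against random lists not matched on level, 3 lists stood apart, without cholesterol synthesis and the chaperones. By the mean 6 did, among them the lysosomal genes (percentiles 98.2 and 99.97). For cholesterol synthesis only Mvk, mevalonate kinase, was past 1.5-fold at 24 h, at -0.69. Of the 16 interferon-stimulated genes 11 were below 0 and 5 above at 24 h.

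Single genes past 1.5-fold in the same direction at both times numbered 49, of which 19 were higher in knockout and 30 lower. Independent lists of these sizes would share 5.95 and 6.55. Genes past 1.5-fold in opposite directions numbered 15 and 13, against 7.01 and 5.56. Lower at both times were Csf1, the macrophage growth factor, at -0.74 and -0.96, Scd1 at -0.67 and -0.95, Ifit1 at -0.70 and -1.07, Ifit3 at -0.62 and -1.06, and Adm, which encodes adrenomedullin, at -0.60 and -0.65. Also lower were Cd248 at -1.06 and -0.86, Bmp1, which trims procollagen, at -0.92 and -0.72, and the stromal marker Pdgfra at -0.62 and -0.97; the stromal list was lower beside them. The immunoglobulin gene Ighm was at -0.63 and -1.14, but at 0.14 and -0.19 with the mean over its probe sets. Rhobtb3 (-0.82 and -1.0), Nexn (-0.78 and -0.80), Svop (-0.75 and -0.81), Klk1b11 (-0.71 and -0.91), Rflnb (-0.70 and -0.81), Nectin1 (-0.66 and -0.87), Rgs16 (-0.65 and -0.73) and Ehd2 (-0.64 and -0.86) completed the 15 lowest. Some of these values rest on arrays near background: the knockout levels were 2.14 and 2.30 for Svop, 1.85 and 2.36 for Rflnb, 2.74 and 2.46 for Klk1b11, and 2.15 at 12 h for Adm.

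Higher in knockout at both times were Rptoros at 1.48 and 1.08, Bcl2a1a at 1.41 and 0.96, Dkk2 at 0.86 and 1.44, Sirpb1c at 1.00 and 0.75, the cytochrome P450 gene Cyp2s1 at 0.74 and 0.96, the myosin light chain gene Myl6 at 0.70 and 0.91, and Polr2l, an RNA polymerase subunit gene, at 0.66 and 0.97. Matn2 was at 0.64 and 1.01, Olfr1077-ps1 at 1.09 and 0.64, Ifna1 at 1.04 and 0.61, and the mitochondrial thioesterase gene Acot9 at 0.59 and 1.03. Olfr1077-ps1 at 12 h and Polr2l at 24 h were near background in wild type, at levels of 2.34 and 2.35. The probe sets of Myl6 and Polr2l were dim over all arrays, with mean levels of 3.88 and 3.14. Across all genes kept, the 2 genotype differences correlated weakly (Pearson's r 0.106, Spearman's rho 0.105; genes are not independent replicates). Past the 60th percentile r was 0.196, and with no level filter 0.0551. The limma fit took its error from the change of the genotype difference between the times. A genotype difference that changed with time therefore counted as noise in it, and the fit says little about such genes. In the limma fit with time as an added term, 0 genes had an adjusted p under 0.05, and 870 of 13354 had an unadjusted p under 0.05. The lowest adjusted p was 0.762, a value shared by Rptoros, Cd248 and other genes. Past the 60th percentile of level 20 genes were past 1.5-fold at both times, and 48 of all genes were when the genes of both mesenchymal lists, which do not hold Cd248 and Bmp1, were left out. The last count reflects membership of these lists and does not tell which of the other genes, Csf1 among them, come from stromal cells.

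**Figure D2:**
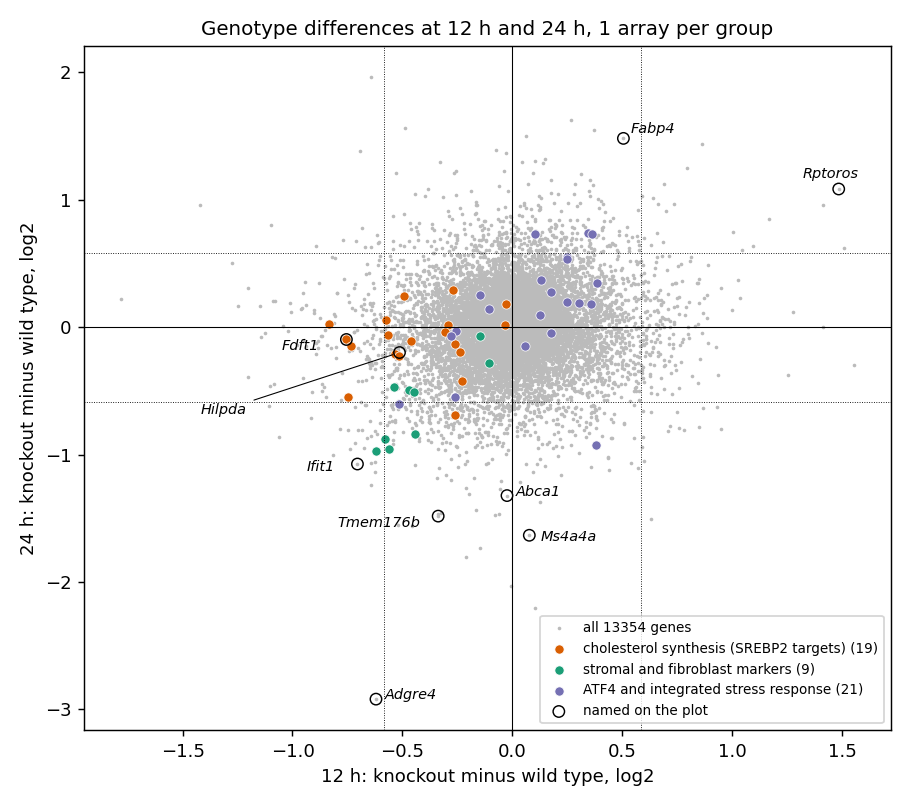
Genotype difference (knockout minus wild type, log2) at 24 h against that at 12 h for 13354 genes, each a grey point, with the genes of 3 lists in colour and dotted lines at 1.5-fold. Cholesterol synthesis genes lie to the left of 0 at 12 h, stromal markers to the lower left, and Hilpda at -0.51 and -0.20.

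Between 12 h and 24 h, the largest differences of wild-type and knockout macrophages were mostly in the same direction. Mrc1, the mannose receptor, was higher at 24 h by 3.19 in wild type and 2.39 in knockout, which is 9.14-fold and 5.22-fold. Slc40a1, the iron exporter ferroportin, was higher by 3.13 and 2.59, the lectin receptor gene Clec4a1 by 2.81 and 1.32, the endothelin receptor gene Ednrb by 2.79 and 1.90, the sodium-proton exchanger gene Slc9a9 by 2.54 and 1.95, and Nxpe5 by 2.35 and 1.69. Adgre4 was higher by 3.77 in wild type and 1.47 in knockout, Ms4a4a by 2.49 and 0.78, and Pilrb1 by 2.19 and 0.17. The knockout 12 h level of Adgre4 was near background, at 2.61. Abca1 was higher by 2.10 and 0.80, and Abcg1, another sterol exporter gene of its list, by 0.62 and 0.47. Ighm was at 2.57 and 2.06, and at 0.53 and 0.20 with the mean over its probe sets.

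Most genes of cholesterol synthesis and of the cell cycle were lower at 24 h in both genotypes. Cholesterol synthesis had a median time difference of -0.68 in wild type, with 14 of 19 genes past 1.5-fold, and of -0.43 in knockout, with 4, both at percentile 0. Fdft1 was at -1.24 and -0.59, Cyp51 at -1.24 and -0.65 and Fdps at -0.91 and -0.72. The 28 cell cycle genes had a median of -0.39 in both genotypes (percentile 0.00 in each), with 8 past 1.5-fold in wild type and 12 in knockout. Of these genes 22 were below 0 and 6 above in wild type, and 21 and 7 in knockout. Ccnb2, cyclin B2, was at -1.24 and -1.46, Plk1 at -0.90 and -1.49 and Kif20a at -0.64 and -1.28. The 19 endoplasmic reticulum chaperones had medians of -0.31 (percentile 0) and -0.17 (percentile 0.11), with 16 below 0 in wild type and 13 in knockout. Hyou1 was at -0.77 and -0.75 and Pdia6 at -0.81 and -0.35, but Herpud1, of endoplasmic reticulum-associated degradation, was higher by 1.13 and 0.65. Fatty acid synthesis genes had medians of -0.21 and -0.13 (percentiles 1.22 and 2.14; in knockout 4.09 by the mean and 3.97 against lists not matched on level), although Scd1 was higher by 0.88 and 0.60. The 24 HIF and glycolysis genes had medians of -0.19 and -0.18 (percentiles 0.12 and 0.00) with the hexokinase gene Hk2 at -0.53 and -0.44; by the mean of the list they lay inside the central 95% (11.4 and 14.6), and its member Adm was higher by 1.71 and 1.66, from 12 h levels near background of 2.75 and 2.15.

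Stromal markers were higher at 24 h, with medians of 0.80 in wild type and 0.51 in knockout (percentile 100 in both) and 7 and 4 of 9 genes past 1.5-fold. The chemokine gene Cxcl12 was at 1.23 and 1.17, Pdgfra at 1.00 and 0.65 and Col3a1 at 0.68 and 0.66. These 6 lists, cholesterol synthesis, cell cycle, chaperones, fatty acid synthesis, HIF and glycolysis and stromal markers, stood apart in both genotypes. Macrophage identity genes had a median of 0.26 in wild type (percentile 100) and 0.02 in knockout (percentile 71.0), with Aif1 at 1.11 and 0.95, C1qa, a complement subunit, at 0.93 and 0.52, and Cx3cr1 at -0.28 and -1.19. Alternative activation markers had medians of 0.36 (percentile 99.8) and 0.13 (percentile 91.7), but of 0.07 and 0.09 without Mrc1, and of 0.10 and -0.02 with no level filter. PPAR target genes had medians of -0.11 (percentile 7.62, and 46.4 by the mean; 0.01 with no level filter) and 0.19 (percentile 99.7). In the last list Pdk4, a kinase that restrains pyruvate oxidation, was higher by 0.97 and 1.64, and Angptl4, a lipoprotein lipase inhibitor, by 0.35 and 0.50. These contrasts between the genotypes were not tested, and every time difference shares its arrays with the genotype differences.

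In wild type 631 genes were higher and 535 lower at 24 h by at least 1.5-fold, with a central 95% range from -0.71 to 0.77; past the 60th percentile of level 346 were higher and 352 lower. In knockout 407 were higher and 433 lower, with a range from -0.63 to 0.63; past the 60th percentile 209 were higher and 225 lower, and after quantile normalization more were higher (448) than lower (379). The 2 genotypes shared 177 higher and 149 lower genes, against 19.2 and 17.3 for independent lists, and 22 went opposite ways, against 36.8. Across genes the 2 time differences correlated at r 0.421 and rho 0.296. The lowest in wild type were the serotonin receptor gene Htr2b at -2.68, Fabp7, a fatty acid-binding protein, at -2.55, Ctla2a at -2.25, Cd24a at -1.96, Tmeff1 at -1.72, the neuropeptide gene Npy at -1.70, Id3, an inhibitor of transcription factors, at -1.67, Kdr at -1.66, P2ry1 at -1.63 and the clock gene Cry1 at -1.59. In knockout the lowest were Id3 at -2.10, Fabp7 at -2.01, the medium-chain fatty acid receptor gene Gpr84 at -2.00, F11r at -1.94, Ctla2a at -1.83, the platelet factor gene Pf4 at -1.81, the mitotic kinesin gene Kif14 at -1.74, Tmeff1 at -1.72, the interferon regulator gene Irf7 at -1.63 and Htr2b at -1.53. Among the highest in knockout were also Zfp772 at 1.76, Myh4 at 1.75, the collagen gene Col8a1 at 1.71 and S1pr3, a sphingosine phosphate receptor gene, at 1.68; the knockout 12 h levels of Myh4 and S1pr3 were near background, at 1.97 and 2.07. With the mean over its probe sets Tmeff1 was at -0.83 in wild type and -0.99 in knockout.

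**Figure D3:**
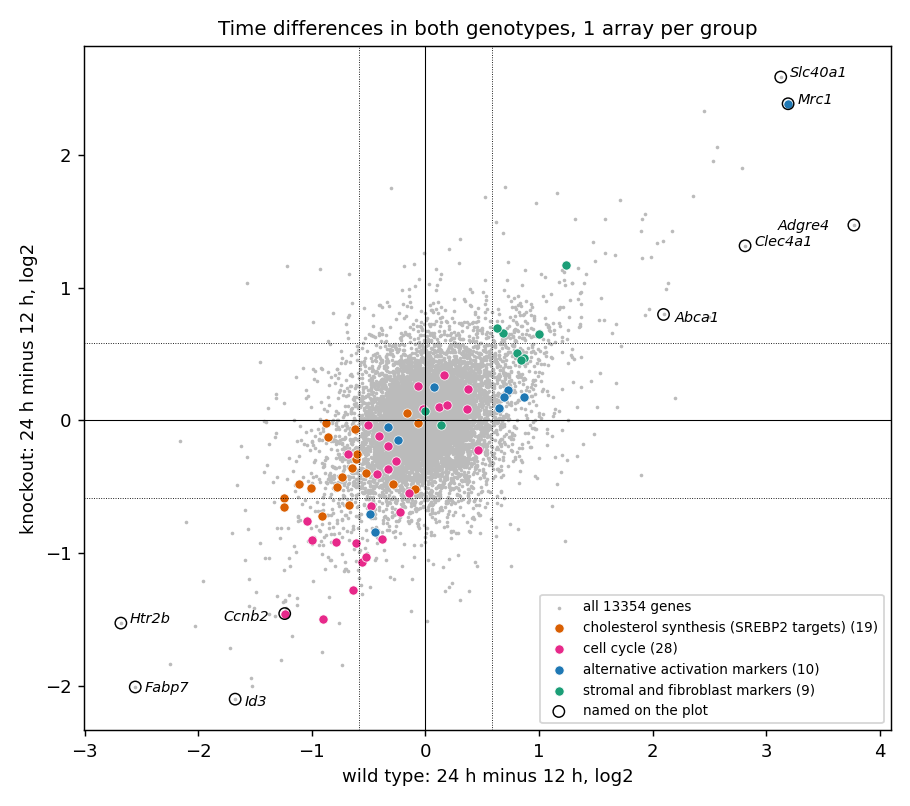
Time difference (24 h minus 12 h, log2) in knockout against that in wild type for 13354 genes, each a grey point, with the genes of 4 lists in colour and dotted lines at 1.5-fold. Cholesterol synthesis and cell cycle genes lie mostly below 0 in both genotypes, and Mrc1 lies at 3.19 in wild type and 2.39 in knockout.

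The genotype difference itself was not the same at the 2 times for some genes, a contrast of all 4 arrays in which 627 genes were higher and 724 lower by at least 1.5-fold. For cholesterol synthesis the difference was less negative at 24 h, by a median of 0.31 over 19 genes (percentile 100), with 5 past 1.5-fold. Lists on the other side were alternative activation at -0.45 (percentile 0.04), dendritic cell markers at -0.27 (2.27), macrophage identity at -0.15 (0.14) and cell cycle at -0.10 (1.97). PPAR targets at 0.19 (99.4), lipid-associated macrophage markers at 0.12 (98.6) and beta-oxidation at 0.12 (97.6) lay on the same side as cholesterol synthesis. Against lists not matched on level, macrophage identity (3.16), cell cycle (5.85), PPAR targets (97.1), lipid-associated markers (88.8) and beta-oxidation (94.0) lay inside the central 95%. The lowest changes were those of Gbp7 at -2.31, Adgre4 at -2.30, Pilrb1 at -2.03, Xlr3a at -1.85 and Olfr1360 at -1.75. The highest were those of Myh4 at 2.05, Zfp944 at 1.78, Zfp932 at 1.73, Rab26os at 1.49 and Prss22 at 1.48, where Myh4 and Prss22 had wild-type 24 h levels of only 2.16 and 2.13. Gbp7 was also dim, at 2.76 in wild type and 2.86 in knockout at 12 h and 2.45 in knockout at 24 h. Xlr3a was at 2.59 in wild type at 12 h. The noise of 4 arrays adds up in this contrast: its SD over the background receptor genes was 0.407 and 14.5% of them lay past 1.5-fold, against 10.1% of the genes kept. Past the 60th percentile of level 498 genes passed, and there more were higher (284) than lower (214).

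The remaining lists with enough members to be placed lay inside the central 95% between the genotypes at both times. Oxidative phosphorylation genes had medians of 0.03 and 0.04 at 12 h and 24 h over 34 members, and -0.10 and -0.06 between the times in wild type and knockout. HIF and glycolysis genes were at -0.05 and -0.00 between the genotypes, NRF2 and oxidative stress genes at -0.01 and 0.11, eicosanoid synthesis genes at -0.02 and -0.02, and osteoclast markers at 0.04 and 0.11, each inside the central 95%. Dendritic cell markers were at 0.08 and -0.17 over 9 genes (percentiles 83.6 and 5.75). Of the markers of other marrow-derived cells few passed the level filter: 1 of 13 for neutrophils (Mmp8, at 0.54 and 0.33), 3 of 9 for B cells (medians -0.54 and -0.41, with all 3 below 0 at both times and Cd79b at -0.65 at 12 h), 3 of 12 for T and NK cells (0.09 and -0.07), 1 of 9 for mast cells and basophils (Kit, at -0.22 and 0.20) and 0 for erythroid cells, of whose 12 symbols 4 were measured here.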

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

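Olfr1360 was the single gene named by the rules that was past 1.5-fold in opposite directions at the 2 times. It was 0.95 higher in knockout at 12 h and at -0.80 at 24 h, so that its genotype difference changed by -1.75. The change was not tested, and no explanation was tested. Olfr1360 belongs to the olfactory receptor family, whose members served here as background, and its mean level was 4.39.

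Probe sets without a single gene name were left aside in the report. Of 9583 such probe sets past the level filter, 485 were past 1.5-fold in the same direction at both times, 266 higher and 219 lower in knockout, where independent lists would share 263. But 454 were past it in opposite directions, against 262, so the excess is nearly as large without agreement between the times and is no sign of a genotype difference by itself. Among the 1118 of these that carry several gene names, 6 were past it in the same direction. Which transcripts the rest measure was not determined here, and no explanation was tested.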

How the results depend on the processing

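Counts of genes past 1.5-fold stayed within 1.5 times of their value under median centring, quantile normalization, loess and the mean over probe sets. But the deposited values were already quantile-normalized, and only 1082 of 22180 genes had more than 1 probe set. These settings therefore had little room to move the counts and say little about stability. Without the genes of both mesenchymal lists, chosen after seeing the data, the counts were 383, 844, 1136, 822, 1348 and 48 for 12 h, 24 h, time in wild type, time in knockout, the change and both times. The 9 and 37 measured genes of these lists are too few to move the first 5 counts by 1.5 times, so these say nothing about stability. The count for both times does not tell which of the remaining genes come from stromal cells. The counts moved with the level filter and fold rule, as these admit more or fewer genes. At 12 h the count was 628 with no level filter, 101 past the 60th percentile, 1321 at 1.3-fold and 34 at 2-fold. At 24 h it was 411 past the 60th percentile, 2287 at 1.3-fold and 103 at 2-fold. For time it was 698, 2728 and 260 in wild type and 434, 2242 and 150 in knockout under those settings. For the change of the genotype difference it was 2316 with no filter, 498, 3138 and 250. At both times it was 20, 252 and 1, and 198 by the mean of both differences. Of the 49 genes called at both times, 49 remained with median centring, 46 with quantile normalization, 47 with loess and 46 with the mean over probe sets. The limma fit with time as a block, which compares the genotypes within each time, gave 0 of 49, with 870 genes at an unadjusted p under 0.05. The correlation of the genotype differences was 0.0551 with no filter and 0.196 past the 60th percentile. That of the time differences was 0.214 without genes past 1.5-fold, which removes the genes that moved most. With random lists not matched on level 3 lists stood apart in place of 5, and 6 by the mean of the list; the cause was not tested. Ighm at 12 h reversed to 0.14 with the mean over probe sets, and 23 further single-gene values moved, all under that setting; 3451 did not. Background signal limits dim genes: 6.71% and 10.6% of genes between the 40th and 60th percentile were past 1.5-fold at 12 h and 24 h, against 1.11% and 4.52% above.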

Other observations

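Of the tests in this part, those of a smaller change in knockout cells and of stromal cells as a source of the cholesterol synthesis difference were chosen only after the result was seen. Among the brighter genes, past the 60th percentile of level and chosen after their values were seen, the lowest genotype differences at 24 h included Ms4a6b at -1.47 and Clec4a1 at -1.37, beside Ms4a4a at -1.63 and the pair Tmem176a and Tmem176b at -1.80 and -1.48. At 12 h these genes were at -0.34, 0.12, 0.08, -0.21 and -0.34. Itga11, an integrin subunit of fibroblasts, was at -1.44 at 24 h and Pot1b, a telomere protein, at -1.22. In the other direction Htr2b was at 1.29, the small GTPase gene Rhov at 1.15 and Cd24a at 1.12, or 0.51 with the mean over its probe sets. Cry2 was at 0.73 at 12 h and -0.05 at 24 h, and Cry1 at -0.07 and 0.85. Hpgd, which inactivates prostaglandins, was at -0.91 and Ptgs2 at -0.84 at 24 h, and Ptges3 at -0.71 at 12 h. Col6a1 was at -0.86 and the smooth muscle actin gene Actg2 at -0.95 at 12 h.

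Lyz2, lysozyme M, whose locus often carries the Cre gene used to delete floxed genes in macrophages, was at -0.21 in knockout at 12 h and -0.38 at 24 h, from levels of 12.6 and 12.8 in wild type. Lyz1, its neighbour with a similar sequence, was at 0.68 and 0.56. Of the 20 genes on either side of Lyz2, 5 were past the level filter; their median differences were 0.13 and 0.08, and Lyz1 was the single one past 1.5-fold, at 12 h. Which Cre line was used is not given in the sources used here, and no explanation was tested.

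More genes were past 1.5-fold between the genotypes at 24 h (865) than at 12 h (387). More noise at background signal at 24 h is argued against as the whole cause. The SD over background receptor genes was only 1.09 times that at 12 h, against 1.51 times over genes past the 60th percentile of level. But the receptor genes had a median level of 1.77, against 6.82 for the brighter genes. Noise that grows with signal would not show in the receptor genes and stays open. A random deviation of the wild-type 24 h array was not decided by the median ratio of wild-type to knockout time change over 150 genes chosen on the knockout arrays, 0.771 (bootstrap 95% interval 0.618 to 0.859), because that choice alone pushes the ratio under 1; past the 60th percentile it was 0.971 over 93 genes, and the reverse ratio over 172 genes chosen on the wild-type arrays was 0.572. A smaller change from 12 h to 24 h in knockout cells may also account for it, since the slope of the genotype difference on the mean time change was -0.25 at 24 h and -0.03 at 12 h. A deviating wild-type array would give such a slope too, and with 1 array per group both stay open, as does a genotype difference that grows with time.

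Stromal and fibroblast markers were lower in knockout at both times, with medians of -0.47 and -0.51. A trend with signal level is argued against, because the higher of these medians stayed at -0.47 after loess. Fewer stromal cells in the knockout cultures may be the source: a second list of 40 mesenchymal genes that shares none with the first, of which 37 were measured, had medians of -0.27 at 12 h and -0.56 at 24 h. The most abundant stromal markers went with it, Bgn from 9.85 to 9.31 and Col1a1 from 8.07 to 7.49 at 12 h. How many of these genes macrophages express themselves was not determined, so a genotype effect on their expression, or a chance difference between cultures, stays open and untested.

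Cholesterol synthesis genes were lower in knockout at 12 h. After loess on level the median stayed at -0.46, which argues against a trend with level. Knockout cells being further along the 12 h to 24 h course as a whole is argued against by percentile 0 among random lists matched on mean time change, whose medians centred on 0.01 with a central 95% from -0.11 to 0.12. At 24 h the median was -0.10, where the second mesenchymal list was lower than at 12 h. That argues against fewer stromal cells only if their share of the signal of these genes stayed the same. The cholesterol synthesis genes had median time differences of -0.68 in wild type and -0.43 in knockout, so a stromal share at 12 h stays open. What set these genes lower stays open, as neither an effect of the genotype nor a chance difference in handling of the single pools was tested.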
